A study of Homo sapiens with 53 samples.

How the data were processed

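RNA was measured by sequencing in 53 libraries from KOLF2.2J, an established human induced pluripotent stem cell line, and from 29 clones derived from it in which a premature termination codon had been introduced, homozygously per the series' design text, into 1 of 9 transcription factor genes. Per the labels, total RNA was taken on day 6 of a differentiation toward primitive syncytium, the first multinucleated trophoblast layer of the human embryo, or, for MAFB, toward extraembryonic mesenchyme. Libraries were made with ribosomal RNA depletion and sequenced on a NovaSeq X, per the labels' protocols. The 53 libraries form 18 groups by knocked-out gene, oxygen label and sequencing run, with 14 wild-type and 39 knockout libraries. Library names separate 4 runs, called A to D here. Run A held the DLX3, MSX2 and VGLL1 knockouts, run B the MAFB knockout, run C the NR2F2 knockout and the ELF5 and ASCL2 knockouts at 20% oxygen, and run D the HIF1A and TP63 knockouts at both oxygen levels with ELF5 and ASCL2 at 3%. Each run had its own wild-type libraries, 2 in run A and 3 per oxygen level in the others. The labels give no oxygen level for run A, run B or the NR2F2 knockout. Knockout replicates were different clones. The design text calls replicates biological, but nothing says whether the wild-type libraries came from separate differentiations, so p-values measure the spread between these libraries, which may be partly technical.

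The authors deposited gene-level read counts that were neither normalized nor filtered, and the submitters' processing notes name STAR, Salmon and featureCounts with the GRCh38 build; their versions, the gene annotation and the strand setting are not given in the sources used here. The main counts are the whole-number featureCounts gene counts as deposited. The deposited estimated counts per gene, which are not whole and match Salmon's output in form, were rounded to whole numbers and used as an alternative. The deposited read counts per category (unmapped, multimapping, no feature, ambiguous) gave the share of reads outside annotated genes, as a percent of all reads of the library. Deposited transcript tables and TPM tables were not used here. Gene identifiers carried no version. Of 36601 gene rows, 36366 matched a symbol, and no row named a non-gene category. Positions are from GENCODE release 29 on GRCh38, which lacked 1985 of the rows. Genes with near-identical copies, such as the chorionic gonadotropin beta and metallothionein genes and those with processed pseudogenes, have uncertain individual counts, and so do overlapping and antisense genes because the strand setting is unknown.

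Counts were analysed in R 4.3.3 with edgeR 4.0.16. Each comparison used the quasi-likelihood test (glmQLFit, glmQLFTest) after TMM normalization and the filterByExpr low-count filter, with 1 mean per group and all groups of the run in the fit. The differences of an effect between oxygen levels for ASCL2 and ELF5, and the comparison of wild types between runs, used their own groups alone because these span runs C and D. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and genes with an adjusted p under 0.05 were called. Every adjusted p for a gene in the text is from this test, and every log2 fold change is the fitted one with its standard error (SE). Levels are CPM, read counts divided by library size and scaled by TMM within the fit, as mean ± SD over the libraries of a group. Wild-type marker levels compared across runs are CPM on a TMM scale shared by all libraries.

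Gene lists, 26 in all, were written from textbook knowledge of trophoblast states, other lineages and pathways. They were tested on voom values of the same fits with camera (limma 3.58.1), with a preset correlation between genes of 0.01, for lists with at least 5 tested members, and adjusted over lists within a comparison. Every adjusted p for a list is from camera. Each list was also tested with an estimated correlation and with fry. For each list the members called over all genes tested, and those past 0.05 adjusted over the list alone, were counted. The genes named in the text follow a fixed rule. It takes the targeted gene; the 6 largest rises and 6 largest falls among called genes with a mean log2 CPM of at least 1, no overlap between the libraries of the groups and an ordinary symbol; and up to 4 called members with the smallest p from up to 5 lists that passed or held many called members. For comparisons of oxygen levels in knockouts and for differences of effects, 4 rises and 4 falls were taken. Exceptions are stated. Groups, tests, lists, this rule and most alternatives were chosen before the data were examined.

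The alternatives were DESeq2-style size factors (RLE), no low-count filter, the deposited estimated counts, DESeq2 1.42.0, a fit of the compared groups alone, leaving out each library in turn, and, between oxygen levels, a block on clone or on wild-type number. After the data were seen, 3 more were added for the comparisons at 3% oxygen: a fit of the 5 groups at 3% oxygen alone, that fit with each library's share of reads outside genes as a covariate, and the TP63 knockout as reference for ASCL2 and ELF5. Another 2 were also added then: that share as a covariate in the fit of run D for comparisons of oxygen levels, and a block on the clones of a knockout used at both oxygen levels for the differences of effects. The pairing for the block comes from clone names: the HIF1A and TP63 clones were the same at both oxygen levels, and the ASCL2 and ELF5 knockouts shared 2 of 3 clones between the levels. The tests of a difference of effects take the libraries as unrelated outside the block. The correlation across genes of deviations from the group mean for a clone's libraries at the 2 oxygen levels was 0.0557, 0.0517 and 0.153 for HIF1A and -0.0500, -0.0385 and 0.0715 for TP63. Wild-type libraries share only a number. Of 52 pairs of libraries within groups, none agreed within sampling noise: the chi-square statistic per gene, over genes with a summed count of at least 20, ran from 3.22 to 98.2. Separate preparations of 1 culture could also exceed that noise, so this does not show that libraries came from separate cultures, and each was counted as 1 replicate on the word of the design text. DLX3 knockout replicate 3, MSX2 knockout replicate 2 and HIF1A knockout replicate 3 at 3% oxygen stood apart from both others of their group by this statistic (98.2 and 58.4, 93.9 and 96.2, and 26.1 and 18.4, against 9.07, 21.4 and 4.42 between the others).

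The test was checked on simulated counts drawn from the real means and library sizes. A list of genes was raised 1.5-fold and counts among the calls, not among the recovered changes. The test then had 200 other changed genes to recover. For the DLX3 comparison (18776 genes in that step) it recovered 4.48% of changes of 1.5-fold, 35.8% of 2-fold and 77.3% of 4-fold. For MAFB (17405 genes) the shares were 61.2%, 73.1% and 93.9%, for ELF5 at 20% oxygen (17484 genes) 44.8%, 79.1% and 89.4%, for TP63 at 20% oxygen (18616 genes) 59.7%, 67.2% and 90.9%, and for the difference of the ELF5 effect between oxygen levels (18451 genes) 17.9%, 59.7% and 89.4%. Unchanged genes made up 7 of 85 calls for DLX3 (8.24%), 12 of 180 for MAFB (6.67%) and 13 of 172 for ELF5 (7.56%). They made up 14 of 177 for TP63 (7.91%) and 8 of 127 for the ELF5 difference (6.30%). The share of false calls was thus above the nominal 5% each time, but no simulation was repeated, so these shares are imprecise. Counted reads per library ran from 8355317 to 39979358, with a median of 26118512.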

Results

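Total RNA was sequenced in 53 libraries of KOLF2.2J cells and knockout clones on day 6 of differentiation to extraembryonic cell types. KOLF2.2J is an established human induced pluripotent stem cell line. In each knockout a premature stop codon had been placed in 1 of 9 transcription factor genes. The DLX3, MSX2, VGLL1, NR2F2, ELF5, ASCL2, HIF1A and TP63 knockouts were differentiated to primitive syncytium and the MAFB knockout to extraembryonic mesenchyme. Each knockout group held 3 libraries from different clones, and wild-type groups held 3 libraries except in run A, which had 2. HIF1A, TP63, ELF5 and ASCL2 knockouts were cultured at 20% and at 3% oxygen. Counted reads per library ranged from 8355317, in NR2F2 knockout replicate 2, to 39979358.

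Marker genes in the wild-type libraries separated both culture schemes. In wild type of run C at 20% oxygen, CGA, which encodes the alpha subunit of chorionic gonadotropin, stood at 7889.2 ± 555 CPM, ERVW-1 (syncytin-1, a cell fusion protein) at 1467.5 ± 118 and GCM1 (a regulator of trophoblast fusion) at 507 ± 18.3 (SD, n = 3). The mesenchymal wild type of run B had 0.0235 ± 0.0210 CPM of CGA and 0.897 ± 0.288 of ERVW-1 (n = 3). It held 4790 ± 226 CPM of COL1A1, a fibrillar collagen gene, and 656 ± 4.95 of VIM, the gene for vimentin, against 61.2 ± 5.41 and 4.003 ± 1.12 in wild type of run C.

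The targeted gene was examined first, in every library. A stop codon does not delete the gene, so its transcript falls where nonsense-mediated decay, which degrades messages with early stop codons, removes it. All 9 altered positions lay in coding sequence on GRCh38. They were at chromosome 17, 49993496 to 49993498 for DLX3, chromosome 5, 174724867 to 174724869 for MSX2, and chromosome X, 136536138 to 136536140 for VGLL1. The MAFB position was on chromosome 20 (40688605 to 40688607), that of NR2F2 on chromosome 15 (96334480 to 96334482), and that of ELF5 on chromosome 11 (34493621 to 34493623). ASCL2 was altered on chromosome 11 (2270129 to 2270131), HIF1A on chromosome 14 (61721598 to 61721600) and TP63 on chromosome 3 (189808374 to 189808376). By GENCODE release 29, the position was in exon 1 of MSX2, MAFB and ASCL2, exon 2 of NR2F2, exon 3 of HIF1A and ELF5, and exon 1 or 2 of DLX3 and VGLL1, depending on the transcript. It was in exon 2 or 4 of TP63. MAFB has 1 exon, so no exon junction follows the stop codon and its transcript does not check the label. ASCL2 has 2 exons, with its coding sequence in exon 1.

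Transcript of the targeted gene fell in the VGLL1, NR2F2, HIF1A and ELF5 knockouts. HIF1A stood at 19.0 ± 3.29 CPM in the knockout and 272 ± 14.6 in wild type at 20% oxygen (log2 fold change -3.84, SE 0.10, adjusted p = 5.09e-22), and at 40.7 ± 3.42 and 149 ± 13.7 at 3% (-1.87, SE 0.09, adjusted p = 5.49e-15). VGLL1 stood at 51.0 ± 7.34 CPM in 3 knockout and 212 ± 21.1 in 2 wild-type libraries (-2.05, adjusted p = 0.000218), and NR2F2 at 139 ± 7.31 and 235 ± 8.43 (-0.75, adjusted p = 5.92e-07). ELF5 stood at 1.85 ± 0.447 against 8.44 ± 0.903 CPM at 20% oxygen (-2.18, adjusted p = 1.89e-05) and at 4.77 ± 0.312 against 11.2 ± 1.68 at 3% (-1.23, adjusted p = 7.68e-08). TP63 fell at 3% oxygen, from 6.45 ± 0.498 to 3.53 ± 0.789 CPM (-0.87, adjusted p = 0.0115), while at 20% it stood at 2.63 ± 0.717 against 3.41 ± 0.221 (-0.37, adjusted p = 0.706). DLX3 and MSX2 rose in their own knockouts. The 3 DLX3 knockout libraries held 1229, 1292 and 2093 CPM against 324 and 289 in wild type (2.33, SE 0.28, adjusted p = 0.00135), and the MSX2 knockout libraries 611, 984 and 610 against 392 and 371 (0.95, SE 0.27, adjusted p = 0.0264). MAFB stood at 10.1 ± 2.31 CPM in the knockout and 6.20 ± 0.0908 in wild type (0.69, adjusted p = 0.368), and ASCL2 at 1.48 ± 0.401 and 2.04 ± 0.618 at 20% oxygen (-0.47, adjusted p = 0.99987) and 0.871 ± 0.216 and 0.790 ± 0.122 at 3% (0.15, adjusted p = 0.808). The transcript thus did not bear out the label of the DLX3, MSX2 and ASCL2 knockouts, nor that of TP63 at 20% oxygen. For ASCL2 the level was low in wild type as well, with SEs of 0.48 at 20% and 0.44 at 3% oxygen. Its transcript could therefore not check the label either way. No library of the VGLL1, NR2F2, HIF1A or ELF5 knockouts overlapped its wild type for the targeted gene.

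**Figure D1:**
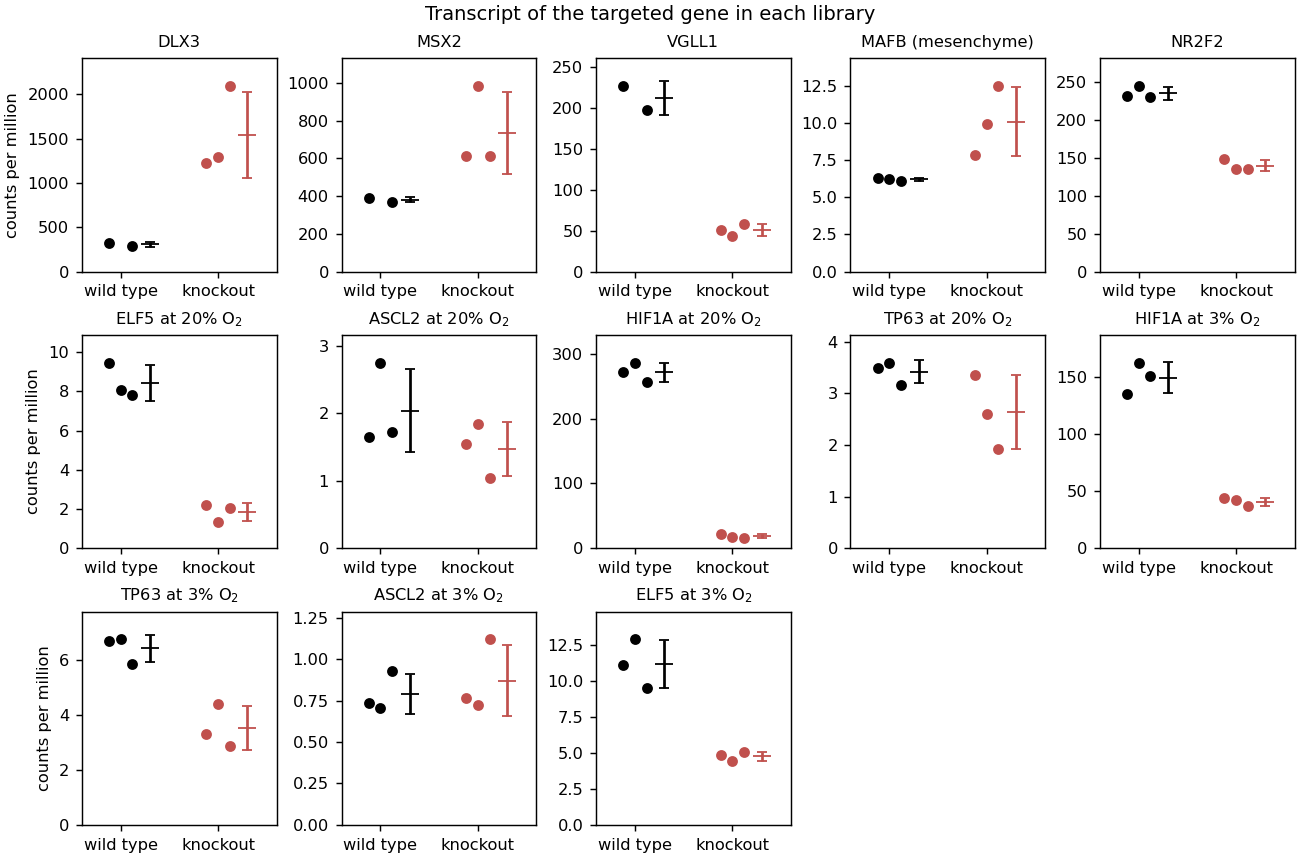
CPM of the targeted gene in each library, wild type in black and knockout in red, with mean and SD beside the points. Knockout points lie below wild type for VGLL1, NR2F2, ELF5 and HIF1A and above it for DLX3 and MSX2, while ASCL2 points overlap at both oxygen levels.

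In the knockout labelled DLX3, a homeobox factor expressed in trophoblast, genes rose that were near silent in wild-type primitive syncytium. The apolipoprotein genes APOA1 and APOC3 rose from 0.336 ± 0.123 and 0.443 ± 0.127 CPM (SD, n = 2) to 16.0 ± 10.6 and 13.0 ± 5.87 (n = 3), with log2 fold changes of 5.55 (SE 0.63, adjusted p = 0.00107) and 4.85 (SE 0.47, adjusted p = 0.000446). TDO2, a tryptophan-degrading enzyme, rose from 0.407 ± 0.0271 to 13.2 ± 6.74 CPM (adjusted p = 0.00036) and FMOD, a matrix proteoglycan, by 5.48 on the log2 scale (SE 0.46, adjusted p = 0.000221). RRAD rose by 6.00 and LSP1 by 4.65. The largest falls included TRIM9, from 46.7 ± 0.241 to 1.45 ± 0.305 CPM (-4.99, SE 0.30, adjusted p = 4.8e-05), the ETS factor ETV5 (-4.85, adjusted p = 0.00197) and DIO3, the enzyme that inactivates thyroid hormone (75.8 ± 2.48 to 3.88 ± 0.901 CPM, adjusted p = 0.000221). SEPTIN3, ESAM and CXCL14 fell by 4.61, 3.91 and 3.90 on the log2 scale.

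Interferon response genes stood higher as a group in the DLX3 knockout. Of 27 tested members 7 rose and 1 fell, and 13 rose and 2 fell when adjusted over the list alone (camera adjusted p = 2.1e-05, adjusted p = 0.475 with an estimated correlation). IFI6 went from 72.6 ± 0.836 to 282 ± 74.9 CPM, IFITM3 from 77.6 ± 5.84 to 168 ± 23.4 and IFITM1 rose by 1.59, while RSAD2 fell by 3.30. Knockout replicate 3 stood apart from replicates 1 and 2 (chi-square per gene 98.2 and 58.4, against 9.07 between those). The median log2 ratio of the list to the wild-type mean was 0.96, 1.10 and 0.37 in replicates 1, 2 and 3. The cytotrophoblast list, of trophoblast progenitor genes, had 2 of 33 members called, DLX3 itself and TP63 (1.36, adjusted p = 0.0111), with 6 rises adjusted over the list alone (camera adjusted p = 0.0143, adjusted p = 0.263 with an estimated correlation). Among p53 targets 3 of 26 rose, GADD45A, PLK3 and BTG2, and 4 rose adjusted over the list alone (camera adjusted p = 0.0184, adjusted p = 0.475 with an estimated correlation). In fits without 1 library, wild type included, 2 to 10 interferon response genes, 1 to 4 cytotrophoblast genes and 0 to 4 p53 targets rose. In all 1528 of 19320 genes were called, 858 up and 670 down. The DLX3, MSX2 and VGLL1 comparisons share 2 wild-type libraries, and leaving out wild-type replicate 1 or 2 gave 232 or 210 calls for DLX3. Without DLX3 knockout replicate 2 there were 921.

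MSX2, another homeobox factor, had the broadest response in run A. Genes that rose included ENPP1, an ectonucleotide pyrophosphatase, from 6.69 ± 1.38 to 290 ± 68.0 CPM (5.44, SE 0.31, adjusted p = 2.49e-06), LVRN (laeverin), a placental aminopeptidase, from 3.09 ± 0.31 to 152 ± 82.6 (5.61, SE 0.57, adjusted p = 8.35e-05), and the zinc finger gene ZNF503 (5.55, SE 0.46). Among the falls, LGALS13, which encodes placental protein 13, went from 11.3 ± 0.168 to 0.252 ± 0.265 CPM (-5.60, SE 0.48, adjusted p = 2.88e-05), the fructose-metabolizing enzyme KHK from 68.2 ± 0.308 to 1.71 ± 1.41, and the plasminogen activator inhibitors SERPINE1 and SERPINB2 fell by 4.19 and 5.04 on the log2 scale. ACVRL1, a receptor for BMP ligands, fell by 5.60 and ESAM by 5.33.

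Lists of other extraembryonic cell types and of some other lineages rose in the MSX2 knockout. The syncytiotrophoblast list fell in 2 of the 3 knockout libraries. In the primitive streak and mesoderm list 4 of 8 rose (camera adjusted p = 0.0190). Neuroectoderm genes rose in 4 of 12 cases (0.0102) and cardiac genes in 5 of 11 (0.0238). The pluripotency and the smooth muscle and contractile lists each had 4 rises and 1 fall among 13 (0.0179 and 0.0164). With an estimated correlation these lists had an adjusted p of 0.318 to 0.508. Knockout replicate 2 stood apart from replicates 1 and 3 (chi-square per gene 93.9 and 96.2, against 21.4 between those). In the extraembryonic mesenchyme list 14 of 33 members rose and 4 fell, 17 and 5 adjusted over the list alone (camera adjusted p = 0.000541, adjusted p = 0.318 with an estimated correlation). BMP4 went from 4.99 ± 0.375 to 77.2 ± 27.0 CPM and VCAN from 6.27 ± 2.18 to 66.7 ± 19.9, while FBN1 fell by 2.96. In the amnion list 11 of 24 rose and 1 fell, 11 and 3 adjusted over the list alone (camera adjusted p = 0.000576, adjusted p = 0.318 with an estimated correlation), with NR2F2 at 1.43 and SEMA3C at 3.17. The syncytiotrophoblast list had 14 falls and 3 rises among 44, 15 and 3 adjusted over the list alone (camera adjusted p = 0.00117, adjusted p = 0.577 with an estimated correlation). Glycolysis genes fell in 7 of 20 cases, GAPDH from 1234 ± 32.8 to 715 ± 38.0 CPM and LDHA from 575 ± 25.9 to 272 ± 47.3, with 8 falls and 1 rise adjusted over the list alone (camera adjusted p = 0.000576, adjusted p = 0.45 with an estimated correlation). Of 49 hypoxia-inducible genes 14 fell and 3 rose, 17 and 4 adjusted over the list alone (camera adjusted p = 0.000541, adjusted p = 0.508 with an estimated correlation). EGLN3, an oxygen-sensing prolyl hydroxylase on this list, moved the other way, from 20.2 ± 8.28 to 655 ± 133 CPM (5.02, SE 0.73, adjusted p = 0.000659). Interferon response genes rose in 13 of 27 cases and fell in 2, with 16 and 2 adjusted over the list alone (camera adjusted p = 0.00039, adjusted p = 0.318 with an estimated correlation). In replicates 1, 2 and 3 the median log2 ratio to the wild-type mean was -1.07, 0.06 and -0.99 over the syncytiotrophoblast list, -0.75, -0.31 and -0.84 over the hypoxia-inducible list and 1.39, 0.35 and 1.37 over the interferon response list. Over the mesenchyme, amnion and glycolysis lists replicate 2 moved like the others (0.66, 0.64 and -0.44). Leaving out 1 library, wild type included, gave 5 to 19 syncytiotrophoblast, 2 to 24 hypoxia-inducible and 3 to 11 glycolysis falls, with 2 to 18 interferon response and 7 to 11 amnion rises. The highest number of falls in each of these 3 lists was without replicate 2. Cardiac rises numbered 0 to 5 and neuroectoderm rises 1 to 5 in fits without 1 library. The MSX2 comparison called 4149 of 19320 genes, 2063 up and 2086 down, and 5087 without replicate 2. Without wild-type replicate 1 or 2 the count was 2023 or 1833.

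VGLL1, a cofactor of TEAD transcription factors, gave fewer calls than DLX3 and MSX2 in the fit of all groups of run A. In fits of each knockout with wild type alone, VGLL1 gave 2420 calls, DLX3 1309 and MSX2 3121. SYNE1, which encodes a nuclear envelope protein, fell from 94.8 ± 2.40 to 3.80 ± 0.744 CPM (-4.63, SE 0.30, adjusted p = 0.000141), PAGE4 from 48.3 ± 3.59 to 5.68 ± 1.36 (-3.08, SE 0.29, adjusted p = 0.000561) and the fibrillin gene FBN1 from 106 ± 6.94 to 15.8 ± 3.44 (-2.74, SE 0.31, adjusted p = 0.00215). ANGPT4, an angiopoietin, rose from 124 ± 2.57 to 661 ± 34.3 CPM (2.42, SE 0.51, adjusted p = 0.0364) and the semaphorin SEMA3G from 3.85 ± 0.431 to 28.1 ± 7.67 (2.86, SE 0.40, adjusted p = 0.0071). BIN2 and ANPEP rose by 2.69 and 2.55, and NCAM1 and CXCL14 fell by 3.00 and 3.09.

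Of 26 integrated stress and unfolded protein response genes 2 rose in the VGLL1 knockout, SLC7A11 and SESN2, and 6 adjusted over the list alone (camera adjusted p = 8.47e-07, adjusted p = 0.828 with an estimated correlation). BMP and TGF-beta targets rose in 2 of 22 cases, ID3 (1.23) and SMAD6 (0.67), and in 7 adjusted over the list alone (camera adjusted p = 0.00291, adjusted p = 0.828 with an estimated correlation). Rises called in these 2 lists numbered 0 to 2 in fits without 1 library. The VGLL1 comparison called 456 of 19320 genes, 234 up and 222 down, with 1349 called by DESeq2 and 2420 in a fit of the VGLL1 knockout and wild-type groups alone. It gave 26 and 27 calls without wild-type replicates 1 and 2, and 78, 301 and 145 without knockout replicates 1, 2 and 3.

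**Figure D2:**
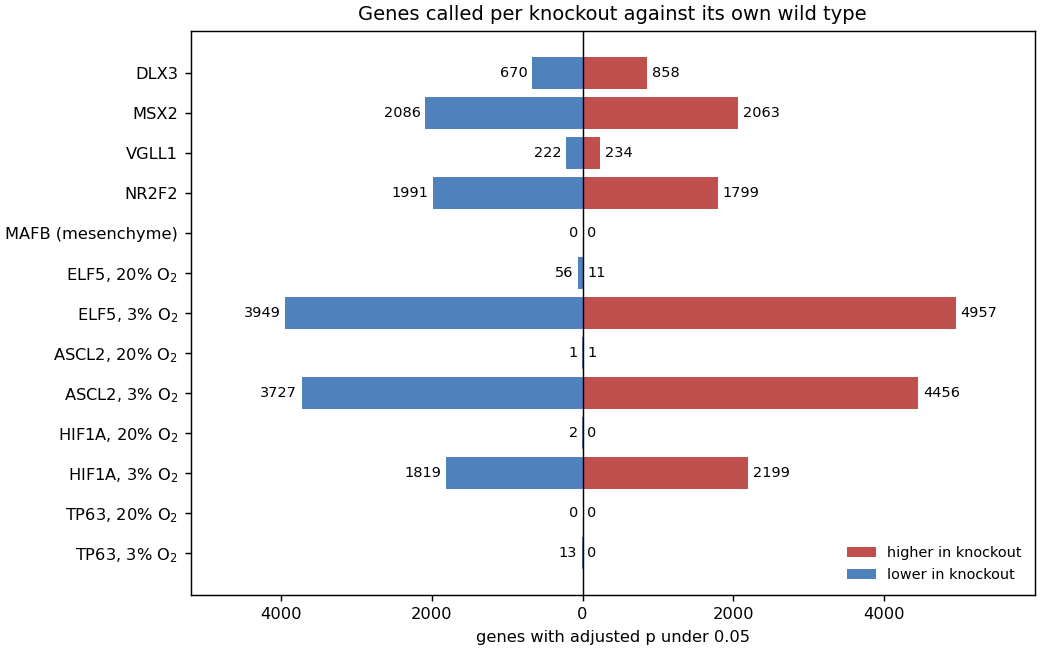
Number of genes with an adjusted p under 0.05 in each knockout against its own wild type, with genes higher in the knockout to the right in red and lower to the left in blue. ELF5 and ASCL2 at 3% oxygen have the longest bars, 8906 and 8183 genes, and MAFB and TP63 at 20% oxygen have 0.

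MAFB was knocked out in the mesenchymal scheme, where no gene passed the threshold. Epithelial genes nonetheless leaned upward as a list: 13 of 25 epithelial junction genes rose when adjusted over the list alone, 0 over all genes tested, with a median log2 fold change of 0.25 (camera adjusted p = 3.23e-16, adjusted p = 0.324 with an estimated correlation). For the surface ectoderm and epidermis list the counts were 8 of 21 and 0 (camera adjusted p = 1.69e-08, adjusted p = 0.21 with an estimated correlation). Other lists leaned up too. Adjusted over the list alone, 7 of 30 cytotrophoblast, 4 of 14 smooth muscle and contractile and 1 of 17 pluripotency genes rose. Their camera adjusted p were 2.52e-06, 0.00084 and 0.000758, and 0.324, 0.401 and 0.21 with an estimated correlation. Lists of cholesterol synthesis, oxidative phosphorylation, proliferation, integrated stress and glycolysis leaned up as well, with 0 members past the threshold either way. Their camera adjusted p were 3.06e-08, 0.000175, 0.000548, 0.00137 and 0.00272, and 0.337 to 0.406 with an estimated correlation. The upward lean was thus not particular to epithelial genes. The extraembryonic mesenchyme list had 0 of 33 members past the threshold either way and a median of -0.09 (camera adjusted p = 1.86e-06, adjusted p = 0.337 with an estimated correlation). The edgeR test called 0 of 17697 genes, with 1475 at an unadjusted p under 0.05 against 885 by chance. DESeq2 called 14, edgeR on the estimated counts 0 and edgeR without the low-count filter 354. Leaving out 1 library gave 0 to 12 rises in the epithelial junction list, 0 to 8 in the surface ectoderm list and 0 to 6 falls in the mesenchyme list. Leaving out MAFB knockout replicate 3 gave 456 calls, and leaving out knockout replicate 1 or 2 or wild-type replicate 3 gave 1.

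NR2F2, a nuclear receptor, was compared with wild type at 20% oxygen in run C. KIT, a receptor tyrosine kinase, rose from 6.84 ± 0.935 to 34.0 ± 6.11 CPM (2.29, SE 0.14, adjusted p = 9.18e-08), and FEZ1 and CREB3L3 by 1.99 and 1.89. The calcium channel gene CACNA1S fell from 6.23 ± 0.287 to 0.45 ± 0.19 CPM (-3.58, SE 0.19, adjusted p = 6.14e-08), DCLK1 from 17.2 ± 0.513 to 2.24 ± 0.698 (-3.09, SE 0.18) and the homeobox gene PITX1 from 24.0 ± 3.57 to 4.74 ± 3.46 (-2.67, SE 0.34). ALOX15B, PADI1 and ADD2 fell by 3.52, 3.43 and 2.72.

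Of 26 integrated stress and unfolded protein response genes 18 fell in the NR2F2 knockout, 21 adjusted over the list alone, and none rose (camera adjusted p = 2.06e-11, adjusted p = 0.39 with an estimated correlation). They included CHAC1, from 24.3 ± 2.38 to 6.70 ± 2.199 CPM, PSAT1 of serine synthesis, from 137 ± 5.65 to 60.1 ± 4.04, and the cystine transporter SLC7A11, from 73.6 ± 4.07 to 36.9 ± 0.851. Proliferation genes rose in 18 of 32 cases and fell in 1, with 20 and 2 adjusted over the list alone (camera adjusted p = 3.56e-07, adjusted p = 0.584 with an estimated correlation). KIF20A rose by 0.81 and CENPF by 0.54. In the extraembryonic mesenchyme list 18 of 32 rose and 5 fell, 19 and 5 adjusted over the list alone (camera adjusted p = 0.000283, adjusted p = 0.444 with an estimated correlation). TWIST1 and LUM rose by 1.34 and 1.04, and PITX1, also a member, fell. Amnion genes rose in 12 of 24 cases and fell in 2, also adjusted over the list alone (camera adjusted p = 0.00346, 0.584 with an estimated correlation). Syncytiotrophoblast genes fell in 11 of 44 cases and rose in 2, 14 and 3 adjusted over the list alone. For that list camera gave an adjusted p of 0.00346 (0.756 with an estimated correlation), and 8 to 19 members fell without 1 library. The hypoxia-inducible list had 10 falls and 3 rises among 49, 12 and 3 adjusted over the list alone (camera adjusted p = 0.000256, adjusted p = 0.756 with an estimated correlation). Glycolysis genes fell in 6 of 20 cases, also adjusted over the list alone (camera adjusted p = 0.000139, adjusted p = 0.658 with an estimated correlation), with HK2 at -0.85 and ENO2 at -1.24. In knockout replicates 1, 2 and 3 the median log2 ratio to the wild-type mean was -0.62, 0.01 and -0.43 over the hypoxia-inducible list and -0.29, -0.08 and -0.32 over the glycolysis list, so replicate 2 hardly shared these falls. By the library names, replicate 2 was sequenced in another lane than the rest of run C, and it was the shallowest library. Clone, lane and depth cannot be told apart there. The labels give no oxygen level for the NR2F2 knockout, while its wild type is labelled 20%. In fits without 1 library 7 to 23 hypoxia-inducible and 4 to 12 glycolysis genes fell, the most without replicate 2, and 8 to 19 proliferation genes rose. Of 17816 genes 3790 were called, 1799 up and 1991 down. Without wild-type replicate 2 there were 2520, and without the shallow knockout replicate 2 there were 4283.

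ELF5, an ETS factor of trophoblast progenitors, was examined at 20% oxygen in run C. Besides ELF5 itself, WNT1, a secreted signalling ligand, fell from 4.44 ± 0.45 to 1.498 ± 0.644 CPM (-1.58, SE 0.29, adjusted p = 0.0361) and DCLK1 from 17.2 ± 0.513 to 9.25 ± 1.81 (-0.90, SE 0.14, adjusted p = 0.0184). ATP12A, a proton-potassium pump subunit, rose from 3.40 ± 0.445 to 7.52 ± 1.42 CPM (1.14, SE 0.17, adjusted p = 0.0184), GPRC5A by 0.91 and WNT7A by 0.68. The integrated stress and unfolded protein response list moved down, with 1 of 26 members called, SLC7A11 (-0.43), and 5 falls adjusted over the list alone (camera adjusted p = 3.54e-10, adjusted p = 0.332 with an estimated correlation), and 0 or 1 called without 1 library. The comparison called 67 of 17816 genes, 11 up and 56 down, with 225 called by DESeq2, 204 without the low-count filter and 24 in a fit of the ELF5 knockout and wild-type groups alone. Counts without knockout replicates 2 and 3 were 17 and 12, and without wild-type replicates 1, 2 and 3 they were 1, 2 and 5.

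ASCL2, a basic helix-loop-helix factor, changed little at 20% oxygen in run C. TGM2, a transglutaminase, rose from 71.3 ± 1.34 to 99.0 ± 9.42 CPM (0.47, SE 0.06, adjusted p = 0.0264) and RPS29, a ribosomal protein gene that has processed pseudogenes, fell from 392 ± 27.6 to 214 ± 10.4 (-0.88, SE 0.10, adjusted p = 0.00663). The extraembryonic mesenchyme list leaned up, with a median log2 fold change of 0.15 and 0 of 32 members called over all genes or adjusted over the list alone (camera adjusted p = 4.56e-06, adjusted p = 0.389 with an estimated correlation). These 2 genes were the calls among 17816, against 0 with the estimated counts and 40 in a fit of the ASCL2 knockout and wild-type groups alone. Either 0 or 1 gene remained in each fit without 1 library: 0 without knockout replicate 3 or wild-type replicate 1 or 3, and 1 without knockout replicate 1 or 2 or wild-type replicate 2.

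Wild-type primitive syncytium at 3% oxygen differed from that at 20% in most tested genes. Between 3% and 20% oxygen in run D, NDRG1, a stress-responsive gene, rose from 27.4 ± 4.37 to 307 ± 13.7 CPM (3.49, SE 0.12, adjusted p = 1.16e-19), PDK1, which restrains pyruvate oxidation, from 14.3 ± 0.658 to 65.0 ± 7.11 (2.18, SE 0.09) and EGLN3 from 21.9 ± 3.00 to 94.7 ± 8.16 (2.12, SE 0.09). PPFIA4 rose from 0.196 ± 0.0249 to 13.5 ± 1.57 CPM (6.07, SE 0.26). Smooth muscle gamma-actin ACTG2 fell by 5.70 on the log2 scale, the oxytocin receptor OXTR from 67.0 ± 6.87 to 1.89 ± 0.499 CPM (-5.14, SE 0.16, adjusted p = 2.9e-20) and cyclin D1 (CCND1) from 27.2 ± 3.10 to 1.04 ± 0.191 (-4.71, SE 0.22).

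Hypoxia-inducible genes rose in 35 of 49 cases and fell in 5, with equal counts adjusted over the list alone (camera adjusted p = 6.42e-07, adjusted p = 0.371 with an estimated correlation). Genes of oxidative phosphorylation fell in 30 of 33 cases and rose in 1, also adjusted over the list alone (camera adjusted p = 7.46e-10, adjusted p = 0.52 with an estimated correlation). NDUFA9 of complex I went from 66.9 ± 3.30 to 22.5 ± 1.82 CPM and COX5A of cytochrome oxidase from 101.3 ± 5.62 to 32.1 ± 4.22. Proliferation genes fell in 23 of 32 cases and rose in 4, and adjusted over the list alone as well (camera adjusted p = 0.00179, adjusted p = 0.644 with an estimated correlation), with CCNB1 going from 441 ± 13.5 to 129 ± 7.08 CPM. Interferon response genes fell in 17 of 26 cases and rose in 3, with the counts unchanged when adjusted over the list alone (camera adjusted p = 0.00551, adjusted p = 0.571 with an estimated correlation). Their examples were MX1, from 71.2 ± 7.10 to 8.12 ± 0.676 CPM, and ISG15, from 36.4 ± 7.08 to 5.02 ± 0.643. In the smooth muscle and contractile list 10 of 13 fell and 2 rose, equally adjusted over the list alone (camera adjusted p = 0.00424, adjusted p = 0.465 with an estimated correlation), with ACTA2 at -3.80 and TAGLN at -2.59. The cytotrophoblast list had 22 falls and 7 rises among 33, the same adjusted over the list alone (camera adjusted p = 0.0125, adjusted p = 0.644 with an estimated correlation). Glycolysis genes went both ways, 6 up and 11 down of 20, also adjusted over the list alone (camera adjusted p = 0.689).

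In wild type 14985 of 19544 genes were called between oxygen levels, 7535 up and 7450 down. The oxygen levels also differed in library composition. Reads outside annotated genes made up 24.8% to 40.1% of all reads in the 15 libraries at 3% oxygen and 10.3% to 14.1% in the 9 libraries of run D at 20%, and mitochondrial genes took 1.5% to 2.35% of counted reads against 3.86% to 5.61%. Size factors by RLE moved the median log2 fold change over all genes from 0.06 to 0.13 in wild type, from 0.06 to 0.12 in the HIF1A knockout and from 0.05 to 0.12 in the TP63 knockout. With each library's share of reads outside genes as a covariate, a fit chosen after the data were seen, 8574 genes were called in wild type, 4003 up and 4571 down. The HIF1A and TP63 knockouts had 9284 and 8816 calls between oxygen levels in that fit. It ended the wild-type calls of ACTG2 (-3.87, adjusted p = 0.0660) and of the proliferation (camera adjusted p = 0.0721), interferon response (0.0868) and cytotrophoblast lists (0.567).

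HIF1A encodes the oxygen-regulated subunit of hypoxia-inducible factor 1. At 20% oxygen the knockout changed LDHA, the enzyme that makes lactate, from 477 ± 48.2 to 298 ± 18.4 CPM (-0.68, SE 0.09, adjusted p = 0.000153), besides HIF1A itself. Of 49 hypoxia-inducible genes 1 fell at 20% oxygen, and 4 adjusted over the list alone (camera adjusted p = 7.23e-13, adjusted p = 0.0915 with an estimated correlation). At 3% oxygen LDHA went from 341 ± 41.9 to 102 ± 11.1 CPM (-1.73, SE 0.09, adjusted p = 3.33e-14), PGK1 of glycolysis from 231 ± 24.5 to 96.7 ± 9.88 (-1.26, SE 0.08), ENO2 from 16.6 ± 1.10 to 4.13 ± 0.853 (-2.00, SE 0.15) and PPFIA4 from 13.5 ± 1.57 to 1.17 ± 0.397 (-3.52, SE 0.19). SERPINE2, a serine protease inhibitor, rose from 40.1 ± 3.69 to 586 ± 29.4 CPM (3.87, SE 0.08, adjusted p = 4.61e-24). ZNF852, KCNK12 and GJD3 rose by 2.71, 2.57 and 2.27, and NCAM1, ALOX15B and FAM162A fell by 2.79, 2.10 and 1.97.

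Glycolysis genes fell in 14 of 20 cases and rose in 1 in the HIF1A knockout at 3% oxygen, the same adjusted over the list alone (camera adjusted p = 2.93e-16, adjusted p = 0.0272 with an estimated correlation). Hypoxia-inducible genes fell in 22 of 49 cases and rose in 2, with 28 and 3 adjusted over the list alone (camera adjusted p = 6.06e-16, adjusted p = 0.0272 with an estimated correlation). These 2 list calls were the ones that held with an estimated correlation, of 165 list calls in all comparisons. Of 43 syncytiotrophoblast genes 25 fell and none rose, with 28 falls adjusted over the list alone (camera adjusted p = 6.06e-16, adjusted p = 0.191 with an estimated correlation). TFPI went from 215 ± 22.5 to 95.7 ± 11.6 CPM, and the near-identical chorionic gonadotropin genes CGB3 and CGB8, whose reads may be split between copies, fell by 1.24 and 1.36. Amnion genes rose in 13 of 23 cases and fell in 3, and adjusted over the list alone as well (camera adjusted p = 4.03e-05, adjusted p = 0.366 with an estimated correlation), GABRP by 1.31 and HAND1 by 1.18. Proliferation genes rose in 14 of 32 cases and fell in 3, with 19 and 3 adjusted over the list alone (camera adjusted p = 1.25e-05, adjusted p = 0.366 with an estimated correlation). MKI67 went from 80.2 ± 6.91 to 121 ± 3.14 CPM.

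At 3% oxygen 4018 of 19544 genes were called in the HIF1A knockout, 2199 up and 1819 down, against 2 at 20% oxygen. With RLE size factors falls were the larger part, 1939 up and 1986 down. The count at 3% was 2290 in a fit of the HIF1A knockout and wild-type groups at 3% oxygen alone. At 20% oxygen DESeq2 called 4 genes and edgeR without the low-count filter 31, and 4 and 5 were called without knockout replicates 2 and 3. The difference between the effects at 3% and 20% oxygen was tested itself, and 1565 genes differed, 784 with a higher and 781 with a lower value at 3%. SERPINE2 differed by 3.69 (SE 0.11, adjusted p = 3.12e-20), ZNF852 by 2.65, NCAM1 by -2.67 and FAM162A by -1.88. In that test the glycolysis list had 11 falls and no rise among 20, with 12 falls and 1 rise adjusted over the list alone (camera adjusted p = 1.14e-11, adjusted p = 0.0966 with an estimated correlation). Without knockout replicate 3 at 20% oxygen 922 genes differed, and without knockout replicates 2 and 3 at 3% oxygen 1025 and 2452. Across genes the log2 fold changes at both oxygen levels correlated at r = 0.0582 (rho = 0.0360), and genes are not independent replicates. With 2 genes called at 20% oxygen, noise in the fold changes there can by itself hold this correlation near 0.

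**Figure D3:**
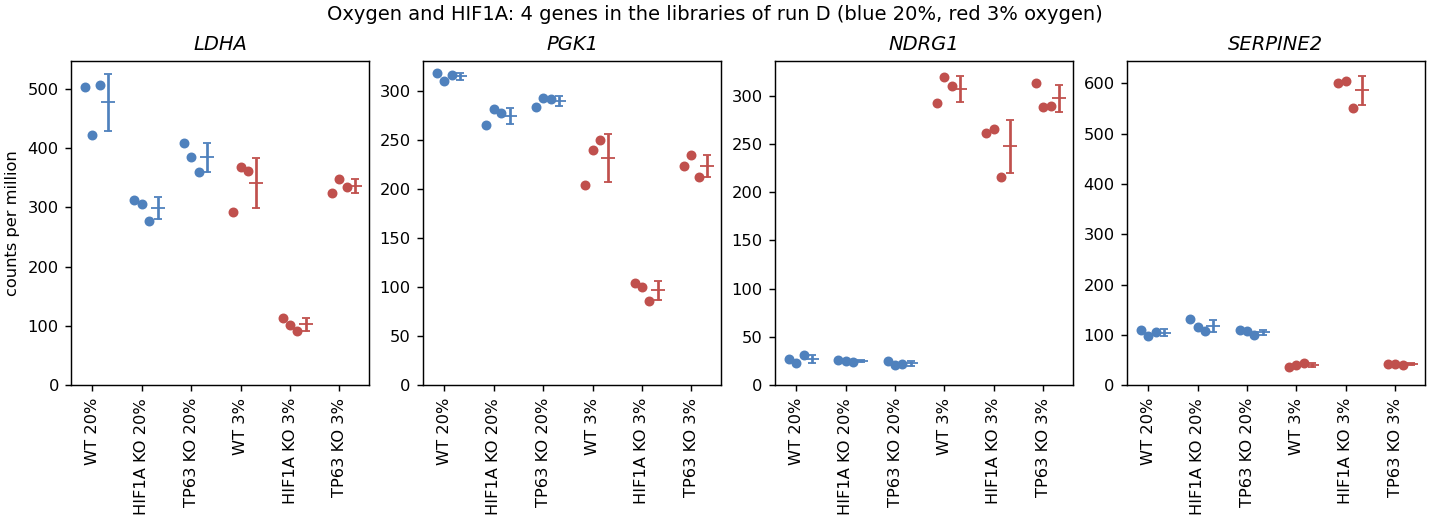
CPM of LDHA, PGK1, NDRG1 and SERPINE2 in the libraries of wild type, HIF1A knockout and TP63 knockout at 20% (blue) and 3% (red) oxygen, with mean and SD beside the 3 points of each group. At 3% oxygen LDHA and PGK1 are lower and SERPINE2 is higher in the HIF1A knockout than in wild type, and NDRG1 is higher at 3% than at 20% in all 3 genotypes.

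Most of the difference between oxygen levels was also present in the HIF1A knockout. In the HIF1A knockout 14534 of 19544 genes were called between 3% and 20% oxygen, 7359 up and 7175 down, and 12814 of the 14985 wild-type calls were called in the same direction and 106 in the opposite one. The correlation of both differences across genes was 0.903, with no library in common. Libraries at 3% oxygen held more reads outside genes in every genotype. With that share as a covariate, calls fell in wild type and in the HIF1A and TP63 knockouts. What the genotypes share thus cannot be assigned to oxygen alone. ACTG2, NTN4 and NCAM1 fell by 5.71, 5.60 and 5.57 in the HIF1A knockout. Hypoxia-inducible genes rose in 31 of 49 cases and fell in 8, equally adjusted over the list alone (camera adjusted p = 0.000903, adjusted p = 0.482 with an estimated correlation). Glycolysis genes fell in 12 of 20 and rose in 4, likewise adjusted over the list alone (camera adjusted p = 0.049, adjusted p = 0.688 with an estimated correlation), and that list's adjusted p was 0.121 in a fit of these 2 groups alone, 0.126 with clone as a block in that fit, and 0.612 with the share of reads outside genes as a covariate.

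TP63, a regulator of epithelial and trophoblast progenitors, gave few changes at either oxygen level. At 3% oxygen PNCK, a calmodulin-dependent kinase gene, fell from 18.5 ± 0.877 to 4.30 ± 0.857 CPM (-2.10, SE 0.15, adjusted p = 2.89e-10), TNNT3, a skeletal troponin, from 7.28 ± 0.503 to 1.77 ± 0.0625 (-2.04, SE 0.24, adjusted p = 1.45e-05) and the creatine transporter SLC6A8 from 251 ± 10.4 to 142 ± 12.6 (-0.83, SE 0.08, adjusted p = 1.59e-06). PKIA and ADGRA3 fell by 0.73 and 0.71. The oxidative phosphorylation list had a median of -0.07 with 0 of 33 members called, also adjusted over the list alone (camera adjusted p = 0.0153, adjusted p = 0.898 with an estimated correlation). At 3% oxygen 13 of 19544 genes were called, all down. Other settings gave 5 to 74 calls, some with rises: 56 by DESeq2 (12 up), 31 with the estimated counts (6 up), 20 with RLE factors (0 up) and 74 without the low-count filter (25 up). A fit of the TP63 knockout and wild-type groups alone gave 7 (1 up), a fit of the 5 groups at 3% oxygen 5 (0 up) and that fit with the share of reads outside genes added 24 (5 up). Counts were 6 without knockout replicate 1, 2 or 3 or wild-type replicate 2, and 5 without wild-type replicate 3.

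At 20% oxygen no gene passed the threshold in the TP63 knockout. The edgeR test called 0 of 19544 genes, with 1316 at an unadjusted p under 0.05 against 977 by chance. DESeq2 called 15, edgeR without the low-count filter 116, edgeR on the groups compared alone 24, and edgeR on the estimated counts 0. Leaving out wild-type replicate 2 gave 19 calls and leaving out knockout replicate 2 gave 1. Camera still called 6 lists, each with 0 members called over all genes tested. The syncytiotrophoblast, hypoxia-inducible, glycolysis, oxidative phosphorylation and integrated stress lists leaned down, and the smooth muscle and contractile list leaned up. Their camera adjusted p ran from 6.69e-05 to 0.0381, and each was 0.938 with an estimated correlation. In the test of the difference between oxygen levels PNCK was called (-1.85, SE 0.29, adjusted p = 0.0105), the 1 gene among 19544. It was not called without TP63 knockout replicate 1 or 3 at 20% or wild-type replicate 1 or 2 at 20%, each of which left 0 calls, and 26 genes were called without the low-count filter and 2 in a fit of the groups compared alone. Between oxygen levels 14557 genes were called in the TP63 knockout, 7215 up and 7342 down, and with RLE size factors 7734 up and 6870 down. Of the wild-type calls 13522 were called in the same direction and 4 in the opposite one, with a correlation across genes of 0.932. PPFIA4 and FOXI1 rose by 6.14 and 5.54, and OXTR and TGFB2 fell by 5.68 and 4.85. Hypoxia-inducible genes rose in 37 of 49 cases and fell in 5, and adjusted over the list alone as well (camera adjusted p = 2.55e-08, adjusted p = 0.229 with an estimated correlation).

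The ASCL2 knockout at 3% oxygen differed widely from wild type. RGS4, a regulator of G-protein signalling, rose from 1.51 ± 0.385 to 33.3 ± 6.37 CPM (4.45, SE 0.23, adjusted p = 6.72e-14), the secreted glycoprotein RELN from 0.303 ± 0.23 to 7.68 ± 2.60 (4.64, SE 0.63), the growth factor receptor PDGFRA from 1.64 ± 0.339 to 13.4 ± 3.17 (3.04, SE 0.21) and the bicarbonate transporter SLC4A4 from 7.59 ± 1.35 to 56.9 ± 8.09 (2.91, SE 0.15). Metallothioneins, small metal-binding proteins with similar sequences, fell: MT1X from 52.2 ± 12.3 to 5.88 ± 0.0747 CPM (-3.15, SE 0.20, adjusted p = 4.03e-12) and MT2A from 70.1 ± 14.0 to 12.0 ± 2.47 (-2.55, SE 0.22). MT1E and MT1F fell by 2.62 and 2.61, and NCAM1 and IL32 by 2.83 and 2.57.

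Proliferation genes rose in 24 of 32 cases and fell in 4 in the ASCL2 knockout at 3% oxygen, 25 and 4 adjusted over the list alone (camera adjusted p = 4.85e-07, adjusted p = 0.739 with an estimated correlation). AURKA and KIF11 rose by 0.91 and 0.90, while E2F1 fell by 1.05. Amnion genes rose in 16 of 23 cases and fell in 4, also adjusted over the list alone (camera adjusted p = 1.73e-05, adjusted p = 0.739 with an estimated correlation), and extraembryonic mesenchyme genes rose in 21 of 33 and fell in 6, 22 and 6 adjusted over the list alone (camera adjusted p = 0.000166, adjusted p = 0.739 with an estimated correlation). HAND1, a member of both lists, went from 26.1 ± 4.98 to 81.7 ± 10.8 CPM, the amnion gene VTCN1 from 23.4 ± 3.59 to 80.8 ± 10.9, and the collagen-binding proteoglycan LUM from 41.4 ± 3.42 to 143 ± 17.8. Syncytiotrophoblast genes fell in 24 of 43 cases and rose in 5, 26 and 6 adjusted over the list alone (camera adjusted p = 4.67e-05, adjusted p = 0.739 with an estimated correlation), with HPGD at -1.26 and HSD17B1 at -1.14. Glycolysis genes rose in 12 of 20 and fell in 2, equally adjusted over the list alone (camera adjusted p = 0.01, adjusted p = 0.739 with an estimated correlation). The comparison called 8183 of 19544 genes, 4456 up and 3727 down. With RLE size factors falls outnumbered rises, 3919 up and 4259 down, as they did with DESeq2, 3814 up and 4104 down, so the larger direction depends on the normalization. Reads outside genes were 28.7% ± 2.12 of all reads in the ASCL2 knockout libraries and 33.8% ± 5.47 in wild type at 3% oxygen (SD, n = 3).

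The ELF5 knockout at 3% oxygen showed changes in many of these genes. RGS4 rose to 30.6 ± 1.80 CPM (4.33, SE 0.23, adjusted p = 1.23e-13), RELN to 5.56 ± 0.969 (4.17, SE 0.64), SLC4A4 to 59.1 ± 2.78 (2.96, SE 0.15) and PDGFRA to 12.8 ± 0.957 (2.96, SE 0.21). MT1X fell to 4.75 ± 0.941 CPM (-3.46, SE 0.21, adjusted p = 1.07e-12) and MT2A to 7.78 ± 2.42 (-3.17, SE 0.23). PCDH9 and VSTM5 rose by 3.03 and 2.92, and TDO2 and BAIAP3 fell by 2.65 and 2.42. Proliferation genes rose in 25 of 32 cases and fell in 3, 25 and 4 adjusted over the list alone (camera adjusted p = 1.53e-08, adjusted p = 0.499 with an estimated correlation), with MKI67 going from 80.2 ± 6.91 to 192 ± 29.1 CPM. Syncytiotrophoblast genes fell in 29 of 43 and rose in 5, also adjusted over the list alone (camera adjusted p = 5.16e-07, adjusted p = 0.499 with an estimated correlation). DYSF went from 797 ± 11.6 to 411 ± 48.6 CPM. Amnion genes rose in 15 of 23 and fell in 3, 16 and 3 adjusted over the list alone (camera adjusted p = 0.00017, adjusted p = 0.499 with an estimated correlation), HAND1 by 2.09 and VTCN1 by 2.07. Of 26 integrated stress and unfolded protein response genes 16 fell and none rose, the same adjusted over the list alone (camera adjusted p = 0.000355, adjusted p = 0.718 with an estimated correlation), TRIB3 by 0.95 on the log2 scale, with 10 to 18 falls in that list without 1 library. The comparison called 8906 of 19544 genes, 4957 up and 3949 down, but 4293 up and 4662 down with RLE size factors and 4180 up and 4527 down with DESeq2. Reads outside genes were 31.5% ± 3.44 of all reads in the knockout libraries.

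**Figure D4:**
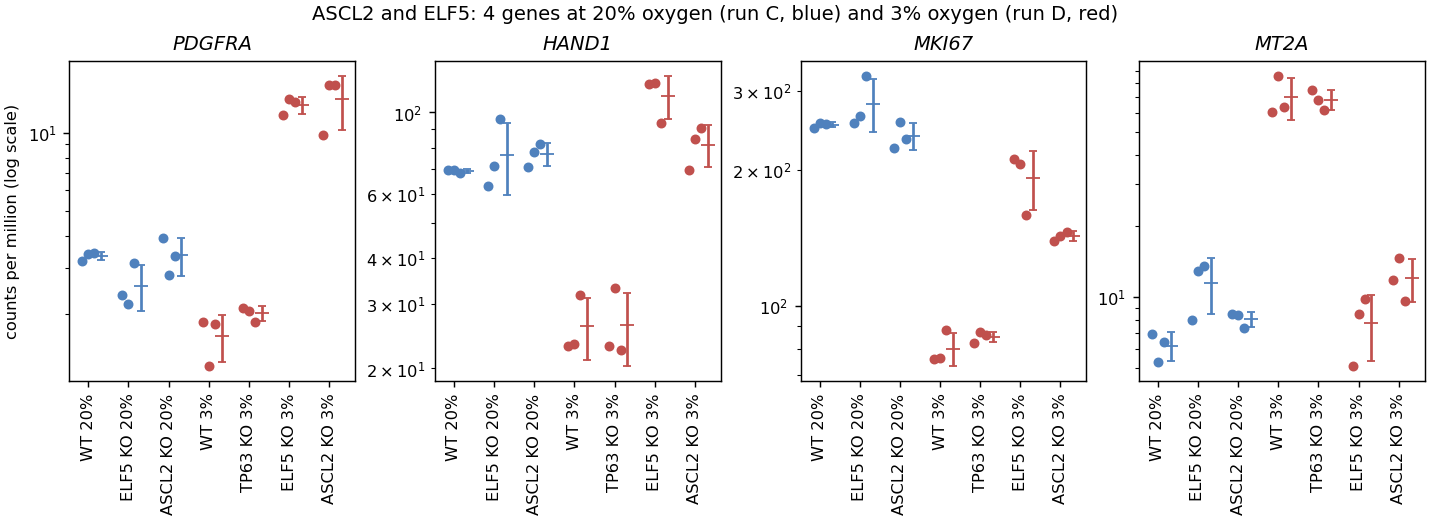
CPM, on log axes, of PDGFRA, HAND1, MKI67 and MT2A in libraries of run C at 20% oxygen (blue) and run D at 3% (red). Mean and SD stand beside the 3 points of each group, and each run is on its own TMM scale. At 3% oxygen the ELF5 and ASCL2 knockouts have higher PDGFRA, HAND1 and MKI67 and lower MT2A than wild type and the TP63 knockout. The HIF1A knockout at 3% oxygen, not drawn here, differed from wild type in the same direction for each of these genes, by less.

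A direct comparison of the ASCL2 and ELF5 knockouts at 3% oxygen, chosen after the data were seen, called 660 of 19544 genes with edgeR, 293 higher in the ASCL2 and 367 higher in the ELF5 knockout. The difference of each knockout's effect between 3% and 20% oxygen was tested across runs C and D, each against its own wild type, with libraries taken as unrelated although 2 of 3 clones of each knockout were used at both oxygen levels. For ASCL2 6007 of 19068 genes differed, 3245 with a higher and 2762 with a lower value at 3%, and for ELF5 4402 of 19224 did, 2452 higher and 1950 lower. RGS4 differed by 4.49 (SE 0.43) for ASCL2 and 4.69 (SE 0.35) for ELF5, and MT1X by -3.35 (SE 0.21) and -4.19 (SE 0.28). Proliferation genes had higher effects at 3% in 21 of 32 cases and lower in 3 for ASCL2, 24 and 3 adjusted over the list alone (camera adjusted p = 7.19e-09, adjusted p = 0.656 with an estimated correlation). For ELF5 the counts were 19 and 2, with 23 and 2 adjusted over the list alone (camera adjusted p = 1.01e-05, adjusted p = 0.917 with an estimated correlation). Oxygen level and run go together in these tests and cannot be told apart. Wild type at 20% oxygen differed between runs D and C in 8712 of 16120 genes, 4587 higher and 4125 lower in run D, with 23 of 26 p53 targets higher, also adjusted over the list alone (camera adjusted p = 2.01e-08, adjusted p = 0.217 with an estimated correlation). Across genes the knockout effects at both oxygen levels correlated at r = 0.0358 (rho = 0.00618) for ASCL2, 0.0963 (rho = 0.143) for ELF5 and, within run D, 0.0812 (rho = 0.140) for TP63. At 20% oxygen 2, 67 and 0 genes were called for these knockouts. Noise in the fold changes there can by itself hold the correlations near 0, so they do not show that the effects disagree.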

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

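The tests of the reads outside genes among libraries at 3% oxygen, of the TP63 knockout as reference and of a round shared by the ASCL2 and ELF5 knockouts were chosen after the results were seen. In 4 cases a knockout's effect differed between 3% and 20% oxygen in a test of the difference itself: 1565 genes for HIF1A, 1 for TP63, 6007 for ASCL2 and 4402 for ELF5.

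Each of these tests was repeated on 60 splits of the libraries, the real one included. As many genes as in the real split were called in 4 splits for HIF1A (real 1565, highest other 2662), 5 for TP63 (real 1, highest other 2), 3 for ASCL2 (real 6007, highest other 6297) and 2 for ELF5 (real 4402, highest other 5311). These splits do not decide on chance for any of the 4. Those that mixed the groups at 3% oxygen removed the large difference at 3% itself and gave at most 1 gene for HIF1A and 0 for the others. Only 4 others kept these groups intact, too few for a share under 0.05, and of them 3 for HIF1A, 4 for TP63, 2 for ASCL2 and 1 for ELF5 reached the real count.

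Comparisons of 3 against 3 libraries allow 10 splits, which cannot give a share under 0.05. The real count and the highest of the other splits were 3790 and 0 for NR2F2, 67 and 0 for ELF5 at 20% oxygen, 2 and 0 for ASCL2 at 20%, and 2 and 1 for HIF1A at 20%. At 3% oxygen they were 4018 and 592 for HIF1A, 13 and 0 for TP63, 8183 and 0 for ASCL2, and 8906 and 7 for ELF5. Between oxygen levels they were 14985 and 0 in wild type, 14534 and 0 in the HIF1A knockout and 14557 and 1 in the TP63 knockout, and between the wild types of runs D and C 8712 and 0. For MAFB and for TP63 at 20% oxygen the real count was 0 and the highest other 0, so all 10 splits were as large; in each of the other comparisons of this kind 1 split, the real one, was.

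The ASCL2 and ELF5 knockouts had 8183 and 8906 called genes at 3% oxygen and 2 and 67 at 20%. With the share of reads outside genes as a covariate among libraries at 3% oxygen, 7515 genes were called for ASCL2 (7355 without it) and 9451 for ELF5 (8139 without it), which argues against that share as the cause. Against the TP63 knockout in place of wild type the counts were 8296 and 8829, so wild-type libraries standing apart do not account for them. The effects of both knockouts, computed with no library in common, correlated at 0.77352 across genes, with 3504 genes up in both (1138 by chance) and 2653 down in both (732 by chance). The labels name no round of their own for these knockouts: the wild-type titles at 3% oxygen name all 4 knockouts, and library numbers run unbroken through the 5 groups, which goes against a separate library round. Culture days are not given, so a culture round shared by these knockouts at 3% oxygen may still lie behind the pattern. A shared biological effect of losing either gene at low oxygen would give the same correlation and stays open, untested. ASCL2 transcript was low and no lower in the knockout at 3% oxygen (0.871 ± 0.216 CPM against 0.790 ± 0.122 in wild type). Its level thus does not show that ASCL2 was lost.

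Most tested genes differed between 3% and 20% oxygen, and the 3% libraries held more reads outside genes. With that share as a covariate in run D, 8574 genes were called between the wild-type groups (4003 up, 4571 down) in place of 14985, and 7653 of the earlier calls kept their direction and call. The share goes with the oxygen level, so what belongs to it and what to oxygen cannot be told apart. Wild types of runs A and C, which also differ in this share (26.4% and 14.1%), differed in a way that correlated at 0.50148 across 17512 genes with the oxygen difference, which is consistent with a contribution of library or RNA quality. Run A carries no oxygen label, so an oxygen difference between those runs is open as well.

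DLX3 and MSX2 transcripts were higher in their own knockouts, by 2.33 and 0.95 on the log2 scale. Reads shared with paralogs are argued against by the estimated counts, which share out reads matching several genes and gave 2.301 and 0.9307. A gain of the chromosome region is argued against by the other tested genes within 2 Mb, whose median log2 fold changes were -0.0029056 for DLX3 (68 genes) and -0.029949 for MSX2 (32 genes). Loss of feedback by the protein on its own gene is a candidate explanation that was not tested, and so are a clone difference outside the targeted gene and a wrong label.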

How the results depend on the processing

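The fits at 3% oxygen with 5 groups, with a covariate and with the TP63 knockout as reference, the covariate between oxygen levels and the block for differences of effects were chosen after the data were seen. Of 301 pairs of a named gene and a comparison, 297 passed the threshold, 249 of these kept direction and call in every alternative run, and 48 lost the call in at least 1, 46 of them in a fit without 1 library. The sign turned for 1, the ASCL2 gene in its knockout at 3% oxygen, which was no call: -0.25914 against the TP63 knockout and -0.075076 without ASCL2 knockout replicate 3, in a range without 1 library of -0.075076 to 0.28954. Of 165 list calls 2 held with an estimated correlation and 93 with fry, and 160 held with RLE size factors. The count of called members in the direction of the list moved more than 1.5 times without 1 library in 46 of the 165, among them 12 of 16 for MSX2, 9 of 11 for MAFB, 6 of 9 for NR2F2 and all 5 for DLX3.

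Without the low-count filter the counts of called genes moved to 354 for MAFB, 204 for ELF5 at 20% oxygen, 31 for HIF1A at 20%, 116 for TP63 at 20%, 74 for TP63 at 3% and 26 for the TP63 difference between oxygen levels. DESeq2 called 1349 genes for VGLL1, 14 for MAFB, 225 for ELF5 at 20%, 4 for HIF1A at 20%, 15 for TP63 at 20% and 56 for TP63 at 3%. The estimated counts gave 0 for ASCL2 at 20% and 31 for TP63 at 3%, where RLE size factors gave 20. Fits of the compared groups alone gave 2420 for VGLL1, 24 for ELF5 at 20%, 40 for ASCL2 at 20%, 24 for TP63 at 20%, 2290 for HIF1A at 3%, 7 for TP63 at 3% and 2 for the TP63 difference, and a correlation between oxygen levels of 0.19092 for TP63. For TP63 at 3% the 5 groups at 3% oxygen alone gave 5 and the covariate 24. With the share of reads outside genes as a covariate in run D, 8574, 9284 and 8816 genes were called between oxygen levels in wild type and in the HIF1A and TP63 knockouts, and 9 list calls and the ACTG2 call in wild type ended. The cause was not tested.

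Leaving out 1 library at a time gave 210 to 1575 called genes for DLX3, 1833 to 5087 for MSX2 and 26 to 301 for VGLL1. With 1 wild-type library left there, it is assumed to vary like the other groups. The range was 0 to 456 for MAFB, 2520 to 4283 for NR2F2, 1 to 55 for ELF5 at 20%, 0 to 1 for ASCL2 at 20%, 2 to 5 for HIF1A at 20% and 0 to 19 for TP63 at 20%. At 3% oxygen it was 2737 to 4697 for HIF1A, 5 to 13 for TP63, 6924 to 7795 for ASCL2 and 7521 to 9099 for ELF5. Between oxygen levels it was 14137 to 14794 in wild type, 13769 to 14515 for HIF1A and 13754 to 14007 for TP63. For the difference of effects it was 922 to 2452 for HIF1A, 0 to 1 for TP63, 5213 to 5969 for ASCL2 and 3314 to 5061 for ELF5, and 7644 to 8345 between wild types of runs D and C. Correlations between oxygen levels ran from 0.0059921 to 0.10572 for HIF1A, 0.027425 to 0.16749 for TP63, -0.02752 to 0.082677 for ASCL2 and 0.0071879 to 0.1328 for ELF5. The syncytiotrophoblast list of ELF5 at 20% had an adjusted p from 1.17e-05, without knockout replicate 1, to 0.62897, without knockout replicate 3, where its direction turned.

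With a block, in a fit of the compared groups alone, the oxygen comparisons called 13613 genes in wild type (by wild-type number), 13262 in the HIF1A and 14028 in the TP63 knockout (by clone), against 13815, 12978 and 14170 in these smaller fits without the block. In the HIF1A knockout between oxygen levels the smaller fit itself ended 2 list calls, epithelial junction (0.0906) and glycolysis (0.121), and with the block they were 0.0603 and 0.126. For the differences of effects a block on shared knockout clones, with the compared groups alone, gave 1646 genes for HIF1A (1336 without the block), 1 for TP63 (2 without it), 5669 for ASCL2 and 4387 for ELF5, and ended 2 list calls, glycolysis for ASCL2 (0.0527) and oxidative phosphorylation for ELF5 (0.0570). Wild-type libraries of like number correlated at -0.0523, 0.0321 and -0.0805 (highest with another number 0.0434, 0.0358 and 0.114). TP63 libraries of the same clone gave values as low, -0.0500, -0.0385 and 0.0715. This check therefore cannot tell whether the wild-type number marks a pairing. The shallow NR2F2 library, with 8355317 counted reads, limits what that comparison can detect among weakly expressed genes.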

Other observations

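The metallothionein genes as a family, the zinc exporter gene SLC30A1, the gene MTF1 and the test of a smaller response to low oxygen were chosen after values were seen. Metallothioneins bind zinc and copper, and all 7 tested members rose in wild type at 3% against 20% oxygen, with a median log2 fold change of 1.78. Against wild type at 3% oxygen all 7 fell in the ASCL2 knockout (median -2.55) and in the ELF5 knockout (median -2.83), 6 of 7 fell in the HIF1A knockout (median -0.71, and 4 of 7 with a median of -0.53 without knockout replicate 3), and none was called in the TP63 knockout (median 0.08). At 20% oxygen none of the 6 tested members was called and the medians lay above 0, at 0.92 in the ELF5 and 0.35 in the ASCL2 knockout. In HIF1A knockout replicates 1, 2 and 3 the median log2 ratio of these genes to the wild-type mean was -0.53, -0.44 and -1.51, so replicate 3 carried much of the fall. Their near-identical copies make the count of each single member uncertain. SLC30A1 fell by 1.08 (SE 0.09, adjusted p = 5.83e-10) in the ASCL2 knockout and by 1.13 (adjusted p = 1.85e-10) in the ELF5 knockout at 3% oxygen on the log2 scale, and rose by 0.67 in wild type at 3% oxygen. In the HIF1A knockout at 3% oxygen its value was 0.03 (adjusted p = 0.880). In run A SLC30A1 rose in the DLX3 (1.42, adjusted p = 0.0264) and MSX2 knockouts (1.69, adjusted p = 0.00488), where no metallothionein was called. The metallothionein medians there were -0.28 for DLX3 and 0.87 for MSX2, with SEs of at least 0.64. Whether they moved with SLC30A1 in run A thus cannot be told. MTF1 fell in wild type at 3% oxygen (-0.29) and in the ASCL2 (-0.32) and ELF5 knockouts there (-0.41). It rose in the MSX2 knockout (0.68, adjusted p = 0.00973).

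Median log2 fold changes per autosome were at most 0.14 in size in the knockout comparisons, with the highest on chromosome 4 for MSX2 (0.143).

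A hypothesis was that the HIF1A and ASCL2 knockouts move genes in a shared direction at 3% oxygen. The HIF1A effect against wild type and the ASCL2 effect against the TP63 knockout, with no library in common, correlated at 0.3867 across genes, which are not independent replicates, above the 0.3 named in advance. The HIF1A and ELF5 effects computed in this way correlated at 0.443. Reads outside genes averaged 30.8%, 28.7% and 31.5% of all reads in the HIF1A, ASCL2 and ELF5 knockouts at 3% oxygen. They averaged 33.8% in wild type and 34.5% in the TP63 knockout there, though HIF1A knockout libraries ranged from 24.8% to 37.8%. The correlations were not recomputed with that share as a covariate, so it is a candidate explanation. A response shared by the genotypes is another, and so is a culture round that sets the TP63 knockout and wild type apart from the others. The labels name no such round and give these groups 1 shared wild type and an unbroken run of library numbers, which goes against a separate library round and leaves separate culture days open.

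Another hypothesis was that the ASCL2 and ELF5 knockouts respond less to low oxygen. Against the TP63 knockout at 3% oxygen their effects correlated with the wild-type difference between oxygen levels at -0.213 for ASCL2 and -0.285 for ELF5 across genes. Of 7535 genes that rose in wild type, 1929 were lower and 1053 higher in the ASCL2 knockout. In the ELF5 knockout 2104 of these were lower and 925 higher. Of 7450 genes that fell, 2529 were higher and 1190 lower in the ASCL2 and 3009 and 1072 in the ELF5 knockout. The 35 hypoxia-inducible genes that rose in wild type, by a median of 1.34, had medians of 0.21122 for ASCL2 (8 lower, 14 higher) and 0.068663 for ELF5 (9 lower, 12 higher). As a set these 35 genes thus stood no lower at 3% oxygen than in the TP63 knockout. Against wild type at 3% oxygen, 21 of 49 hypoxia-inducible genes rose and 9 fell in the ASCL2 knockout. In the ELF5 knockout 20 rose and 13 fell. These values compare levels at 3% oxygen alone. The change between oxygen levels within each knockout was not measured here, so they do not decide whether the list responded less. The hypoxia-inducible genes are also a small part of the genes that differed. A weaker response to low oxygen stays open, untested.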
